A study of Danio rerio with 16 samples.

How the data were processed

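RNA was sequenced from whole zebrafish embryos (Danio rerio, Tropical 5D line) at 48 h post fertilization (hpf). Each of the 16 samples was a pool of 20 embryos, and the labels give 4 biological replicates in each of 4 groups. Embryos carried either a control morpholino or a morpholino against slincR, a long noncoding RNA gene near sox9b. A morpholino is an antisense oligomer that blocks splicing or translation of its target, so a count need not fall in a morphant. From about 6 hpf embryos were kept for 1 h in 1 ng/mL 2,3,7,8-tetrachlorodibenzo-p-dioxin (TCDD), a ligand of the aryl hydrocarbon receptor (AHR), or in 0.1% dimethyl sulfoxide (DMSO, the vehicle). Messenger RNA was selected by its poly-A tail, and libraries were sequenced as paired 150 bp reads on an Illumina instrument.

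The unit of the main table is raw counts per Ensembl gene, as deposited by the authors. The tools named per the submitters' processing notes are FastQC, TopHat, SAMtools, HTSeq and edgeR, with the build GRCz10 and without versions. The settings of alignment and counting, the handling of strand and the annotation release are not given in the sources used here, so overlapping and antisense genes cannot be told apart. Reads in no gene made up 12.78% to 16.06% of the entries counted per library, reads aligned to more than 1 place 24.44% to 29.35%, and ambiguous reads 0.27% to 0.33%. These entries were left out of library sizes and tests. Near-identical genes, such as those for ribosomal proteins, crystallins and complement C3, lose reads that align to several places, and their counts are uncertain.

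The authors also deposited lists of genes past their threshold for TCDD against DMSO in control and in slincR morphants. Per the file headers, these hold log2 fold changes, a mean log2 level, an F score, a p-value and an adjusted p-value. A further column deposited by the authors equals the −log10 of the adjusted p-value. The lists were used for a comparison of calls, for gene symbols and for the biotype of a noncoding RNA. They come from the same samples and are not independent evidence. The authors' tables of enriched processes hold no values per sample and were not used here.

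Counts were normalised by the trimmed mean of M values (TMM). Genes were kept by filterByExpr with its minimum count of 10, which left 20630 of 32266 genes. A quasi-likelihood (QL) negative binomial model with a mean per group was fitted to all 16 samples with edgeR 4.0.16 in R 4.3.3. It had 12 residual degrees of freedom and a biological coefficient of variation of 14%. The 5 contrasts were TCDD against DMSO in control morphants, the same in slincR morphants, slincR against control morphants in DMSO, the same in TCDD, and the difference between both TCDD responses (the interaction). Genes passed at a Benjamini-Hochberg (BH) adjusted p under 0.05 within a contrast, and each adjusted p of a gene is from this edgeR QL test. The standard error (SE) of a log2 fold change is its size divided by the square root of the QL F statistic. Levels are counts scaled by TMM library size (CPM), with the standard deviation (SD) over 4 samples.

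The 26 gene lists, with 738 symbols, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The lists cover the AHR battery, the Nrf2 oxidative stress response, cartilage and sox9 targets, bone, matrix collagens and remodelling, Notch signalling, the p53 and interferon responses, the cell cycle, hypoxia and glycolysis, the circadian clock, ribosomal proteins and cholesterol synthesis. They also hold markers of endothelium, erythroid cells, cardiac and skeletal muscle, neurons, neural progenitors and glia, retina photoreceptors, lens, liver, exocrine pancreas, neutrophils and macrophages, keratinocytes and pigment cells. Of the symbols, 631 matched an identifier, and 97 of these matched by an upper-case name only. The gene table named 26433 of the 32266 identifiers, and upper-case symbols are printed as it gives them. Lists of small respiratory chain subunits and of complement genes were written after the data had been seen.

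The 25 lists with at least 5 tested genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2. The inter-gene correlation was preset at 0.01, and the test was repeated with the correlation estimated for each list. Their p was BH adjusted over the 25 lists within a contrast. A list score is the mean over the list's genes of log2 CPM minus the gene's mean over all samples.

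By the rule for named genes, sox9b was always reported, as slincR would have been if an identifier were paired with it. Up to 8 genes with the largest increase and 8 with the largest decrease were named per contrast, among genes past the threshold with a mean of at least 1 CPM in a group compared, with no overlap between the groups' 4 samples and with a name that is not a clone name. Up to 4 members past the threshold were named per list by smallest p, and where none passed up to 2 could be given as values. The 8 genes with the smallest maximum p over both TCDD contrasts were also named.

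The pipeline was tested on simulated counts with the gene means, dispersions and library sizes of these samples. Of 50 genes changed by each fold in control morphants with TCDD, 52% were called at 1.5-fold, 76% at 2-fold, 100% at 4-fold and 78% at 0.5-fold. A first criterion, a fixed limit on calls of unchanged genes in a single draw, was narrowly missed. It was then replaced by the mean share over 10 draws, a choice made after that failure. Unchanged genes made up 5.36% of the calls on average for TCDD in control morphants, 5.98% for the morpholino with TCDD and 6.62% (5.04% to 10.6%) for the interaction, all above the nominal 5%. No contrast without changed genes had more than 1 call in any of the 10 draws. In the single draw before them, TCDD in slincR morphants, a contrast without changed genes, had 2 calls. Each gene was drawn independently, without variation that many genes of a library share, so these rates need not hold for the real samples. Counts of replicates within each group were compared by chi-square, and the lowest value per degree of freedom was 4.93, so no library was present more than once in a group. Libraries of different groups were not compared.

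Alternatives were DESeq2 1.42.0, limma-voom, relative log expression and upper quartile size factors, no low-count filter or a CPM filter, a replicate block, only the 8 samples compared, stricter thresholds, fry or an estimated correlation for lists, and leaving out each sample in turn. Another was added after the data had been seen: the share of reads in no gene per library, in percent and centred, as a covariate in the edgeR and camera fits. For the comparison of morpholino and TCDD effects its trend within groups was removed from log2 CPM. Counts of calls lost among 24 alternative settings leave out this covariate and the stricter thresholds. Tables were handled with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.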

Results

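Gene expression was measured in 16 samples of 20 whole zebrafish embryos each, in a design with control or slincR morphants and TCDD or DMSO, with 4 biological replicates per group. The total gene count per sample ran from 14977267 to 23142081. The library ConMO_DMSO 4 (control morphants in DMSO, replicate 4) stood apart on the first principal component at −63.4, where the other 15 libraries lay between −17.7 and 19.4. In that library 1111 genes were at least 2-fold below the mean of the other libraries, against 215 to 331 genes in each of the others. The share of reads in no gene averaged 14.13 ± 0.95% and 15.28 ± 1.26% in control morphants in DMSO and TCDD, and 13.70 ± 1.01% and 14.29 ± 1.02% in slincR morphants (SD, n = 4). Over the 16 libraries, each minus the mean of its group, this share had a Pearson's r of −0.95 with the second and 0.83 with the third principal component. A fit with the share as a covariate was added after the data had been seen.

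The gene table pairs no Ensembl identifier with slincR, so its level is not given and the morpholino labels are not checked by it. A noncoding RNA, chosen after its values were seen, had the pattern of a TCDD-induced transcript lowered in slincR morphants: ENSDARG00000097714, a lincRNA in the authors' deposited table. Its level was 0.921 ± 0.287 CPM (SD, n = 4) in control morphants and 8.14 ± 0.353 with TCDD, against 0.0482 ± 0.0366 and 1.36 ± 0.479 in slincR morphants. By the edgeR QL test with BH adjustment, its log2 fold change for the morpholino was −4.00 ± 0.50 (SE) in DMSO, with adjusted p = 4.2e-04, and −2.59 ± 0.26 with TCDD, with adjusted p = 1.0e-05. The fold in DMSO rests on 4 counts over the 4 slincR libraries against 64 over the control libraries. TCDD raised it by 3.13 ± 0.27 in control morphants, with adjusted p = 4.5e-08, and by 4.54 ± 0.48 in slincR morphants, with adjusted p = 1.8e-06. The fold in slincR morphants rests on the same 4 counts in DMSO. The difference between both responses did not pass the threshold.

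The neighbour of slincR, sox9b (ENSDARG00000043923), encodes a transcription factor needed for cartilage. Its level fell with TCDD in control morphants, from 102 ± 12.3 to 70.6 ± 6.7 CPM (SD, n = 4), a log2 fold change of −0.52 ± 0.09 (SE; edgeR QL, BH adjusted p = 0.00442). In slincR morphants it measured 102 ± 8.78 CPM in DMSO and 84.7 ± 3.49 with TCDD, a log2 fold change of −0.27 ± 0.09 that did not pass (adjusted p = 0.404). The responses differed by 0.26 ± 0.13, which did not pass (adjusted p = 1), so a weaker response of sox9b in slincR morphants was not shown. The morpholino left sox9b at a log2 fold change of 0.00 ± 0.09 in DMSO (adjusted p = 0.996) and 0.26 ± 0.09 with TCDD (adjusted p = 0.288). Since sox9b was named in advance, its unadjusted p from the edgeR QL test is also given. That p was 0.00928 for TCDD in slincR morphants and 0.0639 for the difference between the responses. For the morpholino it was 0.973 in DMSO and 0.0107 with TCDD.

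**Figure D1:**
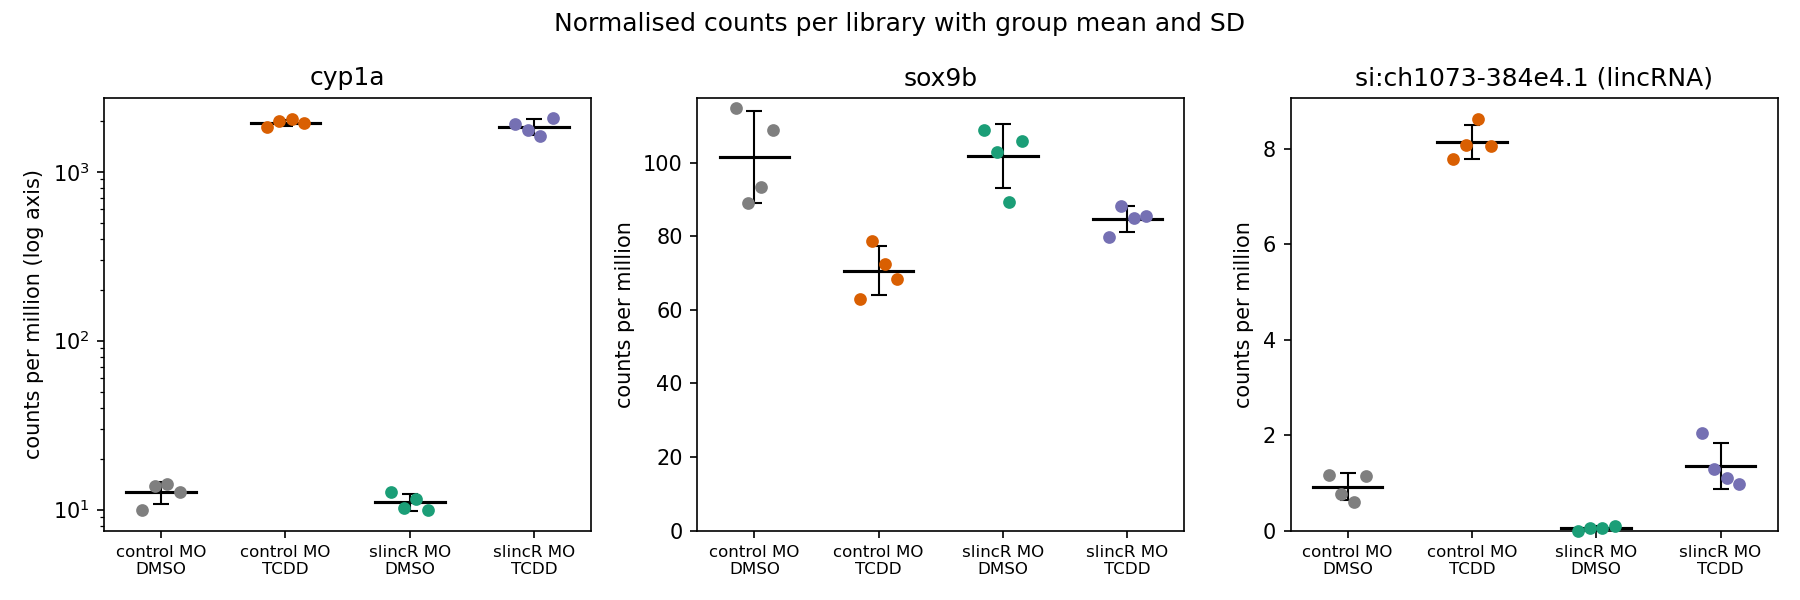
CPM in each of the 16 libraries, by group, for cyp1a (log axis), sox9b and the lincRNA ENSDARG00000097714, with the mean and SD of 4 samples per group. The group means of sox9b were 102, 70.6, 102 and 84.7 CPM, and the lincRNA lay at 8.14 CPM in control morphants with TCDD against 1.36 in slincR morphants with TCDD.

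In control morphants, TCDD raised xenobiotic metabolism genes and AHR feedback genes. The mean of cyp1a, a monooxygenase gene and standard AHR target, was 12.7 ± 1.89 CPM in DMSO and 1950 ± 85.4 with TCDD (SD, n = 4), a 154-fold increase and log2 fold change of 7.27 ± 0.13 (SE; edgeR QL, BH adjusted p = 2.7e-22). The related cyp1c1, cyp1c2 and cyp1b1 rose 37.4-fold, 27.7-fold and 9.99-fold, with adjusted p = 2.5e-20, 7.1e-17 and 8.5e-15. The AHR repressor genes ahrra and ahrrb rose 41.2-fold and 20.1-fold, with adjusted p = 1.8e-11 and 4.5e-08. The growth factor gene fgf7 rose 21.7-fold and wfikkn1, for a secreted protease inhibitor domain protein, 18-fold, with adjusted p = 1.5e-12 and 1.9e-09. The conjugating enzyme gene ugt1b1 rose 4.05-fold and the transcription factor gene foxq1a 5.25-fold, with adjusted p = 4.7e-13 and 2.0e-11. Among genes with a name, a mean of at least 1 CPM in a group and no overlap between the groups' samples, the largest decreases were INHBE, an activin subunit gene, at a log2 fold change of −1.84 ± 0.37 (adjusted p = 0.0157), ponzr4 at −1.30 ± 0.27 (adjusted p = 0.0219), slc2a1a, a glucose transporter gene, at −1.26 ± 0.25 (adjusted p = 0.0128) and the lysozyme gene lyz at −0.90 ± 0.21 (adjusted p = 0.0423). The chemokine gene ccl34b.1, whose groups overlap and which was chosen after its values were seen, fell further, by 2.56 ± 0.58 (adjusted p = 0.0374). The fatty acid binding protein gene fabp11b fell to 0.589 of its level (log2 fold change −0.76 ± 0.11, adjusted p = 4.8e-04). Of 24 alternative settings, the calls of lyz, ccl34b.1, INHBE, ponzr4 and slc2a1a were lost under 12, 11, 4, 4 and 3, and those of lyz and ccl34b.1 also with the share of reads in no gene as a covariate.

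By edgeR's QL test, 128 genes changed with TCDD in control morphants, 97 higher and 31 lower, and 45 of them by at least 2-fold. The count was 264 with DESeq2 and 69 with only the 8 samples compared. With the share of reads in no gene as a covariate it was 283, with 145 higher and 114 of the 128 among them. It was 71, 70 and 78 without ConMO_TCDD replicate 1, 2 and 4, and 100 without ConMO_DMSO replicate 4, of which 85 were among the 128.

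Among the gene lists, the AHR battery stood out in control morphants. Of its 18 tested genes 12 rose and none fell, and 14 rose adjusted over the list alone, with a median log2 fold change of 1.32 (camera adjusted p = 2.5e-47, and adjusted p = 7.9e-07 with an estimated correlation). Of 15 Nrf2 genes 1 rose, nfe2l2a, the gene of a regulator of the oxidative stress response, at 0.61 ± 0.10 (adjusted p = 0.00127), and 4 rose adjusted over the list alone. The list's median was 0.10 (camera adjusted p = 0.0126, and adjusted p = 0.114 with an estimated correlation). The Nrf2 call was lost without ConMO_DMSO replicate 2 or 3 (adjusted p = 0.133 and 0.0515). Of 29 matrix genes 4 rose, with the same count adjusted over the list alone: mmp9 and mmp13a, for matrix-degrading enzymes, at 1.05 ± 0.17 and 1.08 ± 0.24, the collagen gene col12a1a at 0.44 ± 0.08 and TNC (ENSDARG00000078362) at 0.47 ± 0.10. The list's median was 0.08 (adjusted p = 0.0105, and adjusted p = 0.0827 with an estimated correlation). Of 12 bone genes 3 fell, postna at −0.65 ± 0.11, col10a1a at −0.44 ± 0.09 and IFITM5 at −0.64 ± 0.15, and 4 fell adjusted over the list alone. The list's median was −0.20 (adjusted p = 0.00391, and adjusted p = 0.106 with an estimated correlation). The call of IFITM5 was lost under 17 of 24 alternative settings, limma-voom among them, and with the share of reads in no gene as a covariate, and those of mmp13a, col10a1a and TNC under 10, 5 and 4.

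Several tissue and growth lists were lower in control morphants with TCDD, none of them with an estimated correlation. Of 26 lens genes 25 had a negative log2 fold change, with median −0.20, 0 called over all genes and 5 lower adjusted over the list alone (camera adjusted p = 4.0e-05, and adjusted p = 0.114 with an estimated correlation). Of 27 cell cycle genes 25 were negative, with median −0.12 (adjusted p = 2.4e-05, and adjusted p = 0.119 with an estimated correlation). Both lists moved with the share of reads in no gene, with a Pearson's r of −0.78 for lens and −0.80 for the cell cycle over the 16 libraries, each minus its group's mean. ConMO_TCDD 3 had 13.40% of reads in no gene, against 15.77% to 16.06% in the other ConMO_TCDD libraries and 12.78% to 14.99% in ConMO_DMSO. Its lens score was 0.15 against −0.18 to −0.10 in the others, and its cell cycle score 0.03 against −0.18 to −0.10. With the share as a covariate the medians were −0.11 with 20 of 26 negative for lens and −0.10 with 20 of 27 for the cell cycle, each with camera adjusted p = 0.0356. The retina photoreceptor and liver lists had medians of −0.28 and −0.15, both with adjusted p = 0.00391, and adjusted p = 0.114 and 0.106 with an estimated correlation. The retina call was lost without ConMO_DMSO replicate 4 (adjusted p = 0.0503). In the erythroid list cahz, a carbonic anhydrase gene, fell by 0.50 ± 0.11, 7 of 24 genes were lower adjusted over the list alone, and the median was −0.14 (adjusted p = 0.00789, and adjusted p = 0.464 with an estimated correlation). The list's call was lost without ConMO_DMSO replicate 1 or ConMO_TCDD replicate 4 (adjusted p = 0.099 and 0.075), and that of cahz under 9 of 24 alternative settings. The cholesterol synthesis, skeletal muscle and ribosomal protein lists had medians of −0.20, −0.09 and −0.09, with adjusted p = 0.011, 0.0261 and 0.00393, and adjusted p = 0.114, 0.326 and 0.612 with an estimated correlation. The cholesterol synthesis call was lost without ConMO_DMSO replicate 1 (adjusted p = 0.131). The skeletal muscle call was lost without ConMO_DMSO replicate 2 or 4 (adjusted p = 0.133 and 0.11) or ConMO_TCDD replicate 2 or 4 (0.1 and 0.075). The ribosomal protein call was lost without ConMO_DMSO replicate 4 (adjusted p = 0.071) or ConMO_TCDD replicate 2 or 4 (0.1 and 0.0991). With the share of reads in no gene as a covariate the erythroid, skeletal muscle and ribosomal protein calls were lost, with medians of −0.02, −0.03 and 0.05 (adjusted p = 0.268, 0.741 and 0.741), the last with an upward direction. The retina, liver and cholesterol synthesis lists had medians of −0.26, −0.14 and −0.19 (adjusted p = 0.0471, 0.0447 and 0.0191).

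The other lists did not pass in control morphants. Camera gave adjusted p = 0.27 for cartilage and sox9 targets, of which only sox9b fell, 0.364 for Notch signalling, 0.357 for cardiac muscle, 0.73 for neurons, 0.381 for neural progenitors and glia, and 0.153 for the circadian clock. It gave 0.184 for neutrophils and macrophages, of which mmp9 and mmp13a rose and lyz fell. With the share of reads in no gene as a covariate the neural progenitor and glia list and the neutrophil and macrophage list passed downward, both with adjusted p = 0.0471. For pigment cells, the p53 response and endothelium camera without it gave 0.73, 0.793 and 0.898. The endothelial list had a mean of 0.05 but a test direction downward. In the interferon list (adjusted p = 0.709) the median was 0.08 and the mean −0.03, in the keratinocyte list (adjusted p = 0.575) 0.03 and −0.03, and in the hypoxia list (adjusted p = 0.977) −0.01 and 0.01. Only 4 genes of the exocrine pancreas list were tested, with median −0.39 and mean −0.17, and no list test was run on them.

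In slincR morphants TCDD raised the same leading genes. The mean of cyp1a was 11.1 ± 1.29 CPM in DMSO and 1850 ± 203 with TCDD (SD, n = 4), a 166-fold increase (log2 fold change 7.38 ± 0.13, SE; edgeR QL, BH adjusted p = 2.1e-22). The genes ahrra, ahrrb, cyp1c1 and cyp1c2 rose 56.2-fold, 46.9-fold, 36.4-fold and 19.6-fold, and fgf7, wfikkn1 and cyp1b1 21.6-fold, 18.9-fold and 10-fold. The heme-degrading enzyme gene hmox1a rose by 1.09 ± 0.16 (adjusted p = 3.4e-04) and mmp13a by 1.88 ± 0.26 (adjusted p = 1.1e-04). Among genes with a name and no overlap between the groups' samples, the largest decreases were ccl34b.1 at −2.31 ± 0.52 (adjusted p = 0.0484), ponzr4 at −1.38 ± 0.27 (adjusted p = 0.0124), tmem97 at −0.77 ± 0.16 (adjusted p = 0.0222) and lrata, for an enzyme of retinol storage, at −0.75 ± 0.12 (adjusted p = 8.5e-04). The gene ponzr3, whose groups overlap and which was chosen after its values were seen, fell by 1.64 ± 0.35 (adjusted p = 0.033). Of 24 alternative settings, the calls of ccl34b.1, ponzr3, tmem97 and ponzr4 were lost under 13, 7, 6 and 3. In all 79 genes changed, 64 higher and 15 lower. The count was 165 with DESeq2, 125 with only the 8 samples compared and 130 with the share of reads in no gene as a covariate, which held all 79.

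The lists in slincR morphants again had the AHR battery first, with 12 of 18 genes higher, 13 adjusted over the list alone, and a median of 1.28 (camera adjusted p = 2.4e-57, and adjusted p = 2.6e-07 with an estimated correlation). The matrix list had 2 of 29 genes higher, mmp13a and mmp9, 4 adjusted over the list alone, and a median of 0.08 (adjusted p = 5.2e-05, and adjusted p = 0.00396 with an estimated correlation). The circadian clock list had a median of 0.16 (adjusted p = 4.2e-04, and adjusted p = 0.0411 with an estimated correlation). Its members PER1 (ENSDARG00000012499) and bhlhe40 rose by 1.18 ± 0.25 and 0.41 ± 0.09 and rorcb fell by 0.61 ± 0.13, and 4 rose and 1 fell adjusted over the list alone. Of 26 lens genes the crystallin genes crygmx and crygm2d1 fell, at −0.53 ± 0.11 and −0.54 ± 0.12, and 5 fell adjusted over the list alone. The lens median was −0.26 (adjusted p = 1.2e-08, and adjusted p = 0.0541 with an estimated correlation). All 45 ribosomal protein genes were negative, with median −0.24, 0 called over all genes and 11 lower adjusted over the list alone (adjusted p = 7.4e-14, and adjusted p = 0.175 with an estimated correlation). In the Nrf2, cell cycle, cholesterol synthesis and erythroid lists the medians were 0.17, −0.13, −0.15 and −0.14, with adjusted p = 0.00264, 7.4e-06, 0.00225 and 1.4e-04. With an estimated correlation their adjusted p was 0.0541, 0.141, 0.0608 and 0.247. The erythroid call was lost without slincRMO_TCDD replicate 1 (adjusted p = 0.118), whose score of −0.61 lay below the −0.10 to 0.03 of the others. The bone list had a median of −0.21 (adjusted p = 0.04, and adjusted p = 0.175 with an estimated correlation). Its call was lost without ConMO_DMSO replicate 2 or 4, slincRMO_DMSO replicate 2, 3 or 4, or slincRMO_TCDD replicate 2 or 4, with adjusted p of 0.0504 to 0.111. Of 24 alternative settings, the calls of bhlhe40 and mmp9 were lost under 10 each, of crygm2d1 under 6, and of crygmx, PER1 and rorcb under 5 each. All 10 lists past the threshold also passed with the share of reads in no gene as a covariate, where the lens median was −0.22 and the cell cycle median −0.12. The library slincRMO_TCDD 4, with 12.81% of reads in no gene against 14.53% to 15.16% in the other slincRMO_TCDD libraries, had a cell cycle score of 0.02 against −0.10 to −0.04 and a lens score of −0.08 against −0.23 to −0.13.

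Both morphants responded to TCDD in much the same genes. Whether slincR is needed for the response is not settled by this, since its level in the morphants is not known here. Of the genes past the threshold, 56 passed in both, 50 higher and 6 lower, where independence gives 0.301 and 0.0225, and 0 had opposite signs. These contrasts share no libraries. Of the 151 genes past the threshold in either, 145 had the same sign in both, and across these genes, which are not independent replicates, Pearson's r was 0.94. Over all 20630 genes r was 0.36 with a covariance of 0.0333. The interaction test found 0 genes by edgeR QL with 617 at an unadjusted p under 0.05, 0 by DESeq2 with 762, 0 by limma-voom with 662 and 0 with the share of reads in no gene as a covariate, with 1056. Genes past the threshold in 1 morphant only, 72 and 23, are therefore not shown to differ.

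**Figure D2:**
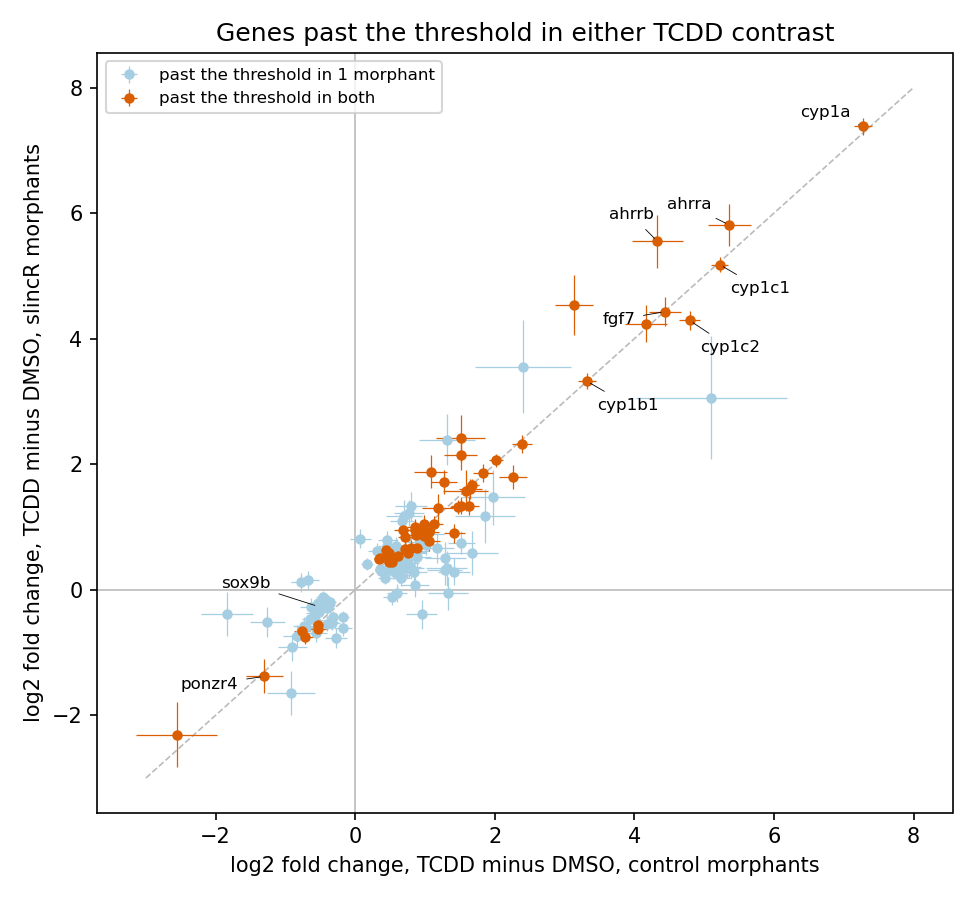
Log2 fold change (TCDD against DMSO) ± SE of the 151 genes past the threshold in either morphant, with control morphants on the horizontal axis, slincR morphants on the vertical axis and a dashed line of equality. Of these genes, 145 had the same sign in both, and cyp1a lay at 7.27 and 7.38.

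Without TCDD, the genes lower in slincR than in control morphants included an amylase gene, some complement genes and a clock gene. The gene amy2al2 fell by 2.25 ± 0.34 (log2, SE; edgeR QL, BH adjusted p = 0.0028). Of 27 complement genes tested, which encode proteins of innate immunity and form a list written after the data had been seen, 5 fell. All 27 had a median of −0.07, with 19 negative. The gene c4b measured 74.2 ± 2.43 CPM in control and 44.0 ± 4.19 in slincR morphants (SD, n = 4). Its log2 fold change was −0.75 ± 0.09 (adjusted p = 4.2e-04). The fold changes of c3a.3, cfb and c3a.1 were −1.08 ± 0.17 (adjusted p = 0.00346), −0.73 ± 0.10 (adjusted p = 9.7e-04) and −0.52 ± 0.09 (adjusted p = 0.00538). The cryptochrome gene cry3a, of the circadian clock list, fell by 0.57 ± 0.07 (adjusted p = 4.8e-04). A mitochondrial creatine kinase gene, CKMT2 (ENSDARG00000069615), fell by 1.53 ± 0.24 (adjusted p = 0.0035). The genes tmem86b, gbp2 and SLC2A6 fell further than the 5 complement genes, to 0.249, 0.414 and 0.415 of their level in control morphants. Their adjusted p was 0.049, 0.0202 and 0.049. Of 24 alternative settings, the calls of tmem86b, gbp2 and SLC2A6 were lost under 16, 6 and 15. Among genes with a name and no overlap between the groups' samples, the highest increases were rnf213b, a ubiquitin ligase gene, at 1.65 ± 0.22 (3.15-fold, adjusted p = 5.6e-04) and the helicase gene HFM1 at 0.76 ± 0.13 (1.69-fold, adjusted p = 0.00538). A gene without a name, ENSDARG00000097834, chosen after its values were seen, rose by 1.14 ± 0.17 (adjusted p = 0.00173).

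In DMSO, 31 genes changed with the morpholino, 4 higher and 27 lower. The count was 95 with DESeq2, with 32 higher, 54 without a low-count filter, 99 with the share of reads in no gene as a covariate, which held all 31, and 17 with only the 8 samples compared. It was 52 without ConMO_DMSO replicate 2, 20 without slincRMO_DMSO replicate 2 and 17 without slincRMO_DMSO replicate 3. When the samples were split in other ways, 2 of 35 splits, the real one included, gave at least as many genes. The highest other gave 167, so chance is not excluded for this count.

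Of 45 ribosomal protein genes 3 fell with the morpholino in DMSO, RPL35 at −0.82 ± 0.16, rps20 at −0.61 ± 0.10 and RPS12 at −0.46 ± 0.10, and 21 fell adjusted over the list alone. The median was −0.27 (camera adjusted p = 5.6e-15, and adjusted p = 0.199 with an estimated correlation). The call of RPS12 was lost under 18 of 24 alternative settings, both other size factors among them, that of RPL35 under 8 and that of rps20 under 1. The neutrophil and macrophage list had 17 of 20 genes negative, with median −0.34, 0 called and 0 adjusted over the list alone (adjusted p = 4.4e-04, and adjusted p = 0.133 with an estimated correlation). The retina photoreceptor list had 16 of 17 negative and median −0.27 (adjusted p = 0.00318, and adjusted p = 0.133 with an estimated correlation). Of the keratinocyte list icn2 fell by 0.65 ± 0.13, and the median was −0.13. Its adjusted p was 0.00635, 0.133 with an estimated correlation and 0.0552 without ConMO_DMSO replicate 4, and the call of icn2 was lost under 16 of 24 alternative settings. The Notch list was higher, with median 0.10, 0 called and 3 higher adjusted over the list alone (adjusted p = 0.00635, and adjusted p = 0.133 with an estimated correlation). The p53 list, which often rises as a side effect of morpholinos, had a median of −0.12 (adjusted p = 0.0261, and adjusted p = 0.283 with an estimated correlation) and lost its call without ConMO_DMSO replicate 1 or 4 or slincRMO_DMSO replicate 1 (adjusted p = 0.103, 0.132 and 0.159). The circadian clock list had a median of 0.17 (adjusted p = 0.0486, and adjusted p = 0.199 with an estimated correlation). Its call was lost without ConMO_DMSO replicate 1 or 2, ConMO_TCDD replicate 1 or 3, slincRMO_DMSO replicate 3 or 4, or slincRMO_TCDD replicate 1, 2 or 3, with adjusted p of 0.0512 to 0.176. With the share of reads in no gene as a covariate the p53 and circadian clock calls were lost (adjusted p = 0.0865 and 0.0534), and the other 5 lists passed.

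With TCDD present, ribosomal protein genes were lower in slincR than in control morphants. Of 45 tested, 13 fell over all genes tested and 34 adjusted over the list alone, where 1 rose. Their median was −0.42, with 41 negative (camera adjusted p = 1.5e-25, and adjusted p = 0.14 with an estimated correlation). Examples were RPL24 at −1.09 ± 0.17 (SE; edgeR QL, BH adjusted p = 0.00337), RPL35 at −1.07 ± 0.16 (adjusted p = 0.00271), RPS15 at −0.69 ± 0.10 (adjusted p = 8.9e-04) and RPS12 at −0.59 ± 0.10 (adjusted p = 0.00337). The score of the list per library averaged 0.13 ± 0.19 in control and −0.30 ± 0.11 in slincR morphants with TCDD (SD, n = 4), and an exact two-sided permutation test gave p = 0.0286, the smallest that 4 against 4 allows. The score had a Pearson's r of −0.80 with the share of reads in no gene over the 16 libraries, each minus its group's mean. With that share as a covariate the median was −0.54, with 34 genes lower over all genes tested. Small respiratory chain subunits, a list written after the data had been seen, moved the same way, with a median of −0.27 over 51 genes, 44 of them negative. A chance difference between libraries and a lower recovery of short mRNAs stay open as sources of the lower ribosomal protein counts.

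The amylase gene amy2al2 fell by 2.37 ± 0.35 with TCDD (adjusted p = 0.00194), CKMT2 (ENSDARG00000069615) by 1.58 ± 0.25 (adjusted p = 0.00316) and cry3a by 0.72 ± 0.07 (adjusted p = 1.1e-05). The circadian clock list had 1 gene higher, PER1 (ENSDARG00000012499) at 1.17 ± 0.25, and 2 lower, cry3a and rorcb, the latter at −0.73 ± 0.13. Adjusted over the list alone 12 rose and 2 fell, with median 0.22 (adjusted p = 3.0e-04, and adjusted p = 0.067 with an estimated correlation). Other increases were rnf213b at 1.17 ± 0.22 (adjusted p = 0.0129), GNMT, a methyltransferase gene, at 0.99 ± 0.19 (adjusted p = 0.0165), HFM1 at 0.94 ± 0.13 (adjusted p = 7.1e-04) and hmox1a at 0.77 ± 0.16 (adjusted p = 0.0208). The p53 regulator gene mdm2 fell by 0.63 ± 0.12 (adjusted p = 0.0134) and the pigment gene SLC45A2 by 0.45 ± 0.09 (adjusted p = 0.0152). Of 24 alternative settings, all of those lost being leave-outs, the call of PER1 was lost under 7, those of GNMT and hmox1a under 5, those of mdm2 and SLC45A2 under 4, that of rnf213b under 3 and that of rorcb under 1.

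With TCDD, 92 genes changed with the morpholino, 17 higher and 75 lower. The count was 247 with DESeq2, 180 with only the 8 samples compared and 287 with the share of reads in no gene as a covariate, which held all 92. With that covariate the erythroid and lens lists also passed, downward (adjusted p = 0.0299 and 0.0368). It was 39, 59 and 43 without ConMO_TCDD replicate 1, 2 and 3, and 32, 22 and 45 without slincRMO_TCDD replicate 1, 2 and 4. With and without TCDD, 18 genes passed in both, 3 higher and 15 lower, where independence gives 0.0033 and 0.0982, and 103 of the 105 genes past the threshold in either had the same sign in both.

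**Figure D3:**
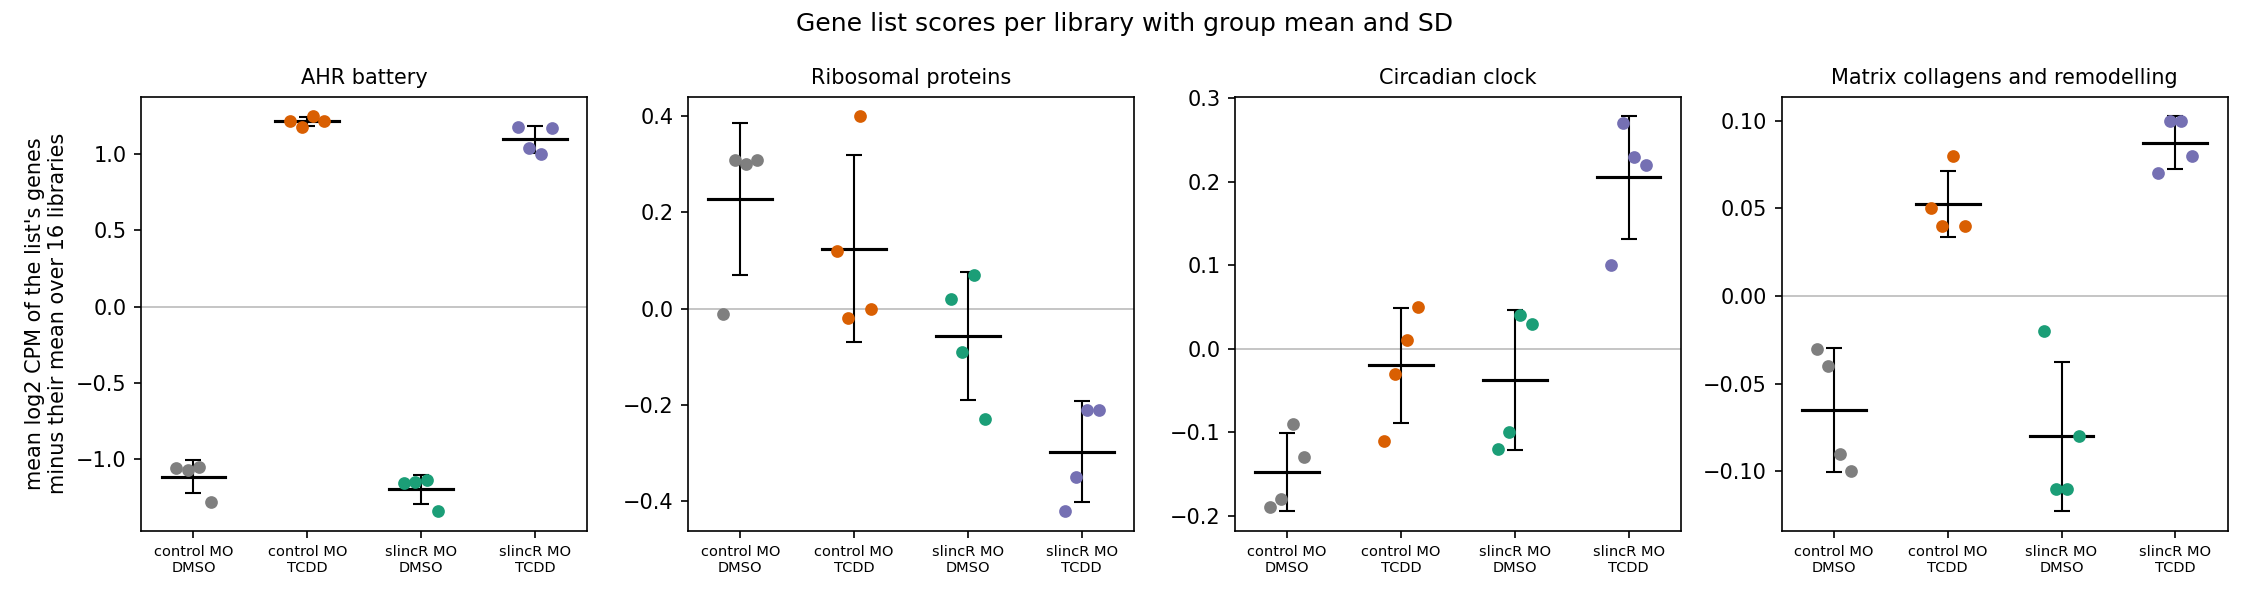
Scores per library (mean log2 deviation of the list's genes from their mean over all libraries) of the AHR battery, ribosomal protein, circadian clock and matrix lists in the 4 groups, with the mean and SD of 4 samples. The ribosomal protein score averaged 0.23, 0.13, −0.05 and −0.30 in control and slincR morphants without and with TCDD, in the order control DMSO, control TCDD, slincR DMSO and slincR TCDD.

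The effect of the morpholino in DMSO was compared with that of TCDD in control morphants, which asks whether the slincR morpholino acts like TCDD. No gene passed in both with the same sign, where independence gives 0.0188 higher and 0.0406 lower. With expected counts this low, 0 cannot show fewer shared genes than chance gives. The 1 gene that passed with opposite signs was the lincRNA ENSDARG00000097714, higher with TCDD and lower with the morpholino. These contrasts share the ConMO_DMSO libraries, which alone gives a Pearson's r of 0.50 and a covariance of 0.0264 in simulated unchanged groups. The unsplit values were 0.35 and 0.0293. With the shared libraries divided so that no library was used in both, the mean r over 6 splits was −0.05 (−0.12 to 0.05) and the mean covariance −0.00688 (−0.016 to 0.00545), across genes, which are not independent replicates.

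The authors' deposited lists hold 132 genes for TCDD in control morphants, 101 higher and 31 lower, and 80 in slincR morphants, 66 higher and 14 lower. Of these, 125 and 76 also passed here, all 132 and 80 had the same sign, and the median difference in log2 fold change was 0.00. The genes on the authors' lists alone had an adjusted p of at most 0.0587 and 0.0623 here.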

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

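Among the tests below, that of the remaining complement genes was set before its result was seen; the tests on short mRNAs, on the ribosomal protein score, on the share of reads in no gene, on the lincRNA and on liver genes were chosen only after the result was seen. Samples were compared with the others of their group in 148 groups of 4 values, and 9 stood apart by Dixon's test, where chance gives about 1 in 20 groups.

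The share of reads in no gene was 13.4% in ConMO_TCDD 3 (others 15.8% to 16.1%) and 15.2% in slincRMO_DMSO 4 (others 13.1% to 13.4%). The second principal component was 6.7 in slincRMO_DMSO 4 (others 23.6 to 24.1). The AHR battery score was −1.28 in ConMO_DMSO 4 (others −1.07 to −1.05) and −1.34 in slincRMO_DMSO 4 (others −1.16 to −1.14). The cardiac muscle score was 0.08 in ConMO_DMSO 3 (others −0.1 to −0.07), and the skeletal muscle score −0.06 in slincRMO_DMSO 4 (others 0.06 to 0.07). The ribosomal protein score was −0.01 in ConMO_DMSO 1 (others 0.3 to 0.31), and the cholesterol synthesis score −0.05 in slincRMO_TCDD 1 (others −0.17 to −0.16). Of these 9 values 4 came from slincRMO_DMSO 4. Within groups the share of reads in no gene had a Pearson's r of −0.95 with the second principal component, −0.85 with the skeletal muscle score and −0.80 with the ribosomal protein score over the 16 libraries, so these values are not independent of each other. What sets this share was not tested.

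The TCDD response of the ribosomal protein list differed between slincR and control morphants by the interaction test (camera adjusted p = 0.0097, median −0.15), with adjusted p = 0.888 with an estimated correlation. The call was lost without ConMO_DMSO replicate 1 (adjusted p = 0.677), ConMO_TCDD replicate 3 (0.595), slincRMO_DMSO replicate 1 (0.125) or 3 (0.205), or slincRMO_TCDD replicate 1 (0.271) or 2 (0.0714). With the share of reads in no gene as a covariate the adjusted p was 1.8e-07 and the median −0.21.

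Ribosomal protein genes were lower in slincR morphants with TCDD. Against a difference between libraries along the share of reads in no gene, as the whole cause, the median was −0.54 with that share as a covariate (95% bootstrap interval of the median −0.64 to −0.49) and −0.42 without it. The interval was drawn over the list's genes, which are not independent, and leaves out the spread between libraries. A chance difference between libraries stays open: the exact permutation test of the score gave p = 0.0286, the smallest the design allows, and the list was picked among 25 after its values were seen. A lower recovery of short mRNAs in some libraries also stays open, since the small respiratory chain subunits, which also have short mRNAs, had a median of −0.27. That value is consistent with a technical source, though a joint change of both gene groups in the embryos could give it too and was not tested.

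A lincRNA, ENSDARG00000097714, was lower in slincR morphants. Mislabelled samples stay open: 0 libraries lay within the range of the other morpholino group at the same treatment, but the lincRNA was picked because it parts these groups, so this tests nothing. That the lincRNA is slincR itself may be so and stays open, since the gene table pairs 0 Ensembl IDs with slincR, although 1 RefSeq gene carries the name as a synonym. Whether the lincRNA is the transcript the morpholino was made against or another transcript was therefore not told apart here.

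In slincR morphants without TCDD 5 of 27 complement genes were lower, with a median of −0.73; the fifth, c5, was chosen after its values were seen. Against fewer liver cells, as the whole cause, the 22 genes of the liver list had a median of 0.01 (95% bootstrap interval of the median −0.15 to 0.05). Of these 22 genes, 2 are among the 5. The interval was drawn over genes and leaves out the spread between libraries. Whether complement genes fell as a group is open: the other 22 had a median of −0.04, but they are what the threshold left over, so this decides nothing. Over all 27 the median was −0.07 and camera gave p = 1.2e-05 downward, and p = 0.00278 with an estimated correlation, but the list was written after the 5 had been seen. A change in these 5 genes within liver cells is a hypothesis that may hold and was not tested.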

How the results depend on the processing

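The alternatives and the other splits of the samples were planned, except that the share of reads in no gene as a covariate was added, and the number of splits drawn for the interaction chosen again, after the results were seen.

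Other splits of the samples were set against the real one. For the 128 genes changed by TCDD in control morphants, only the real split gave as many (1 of 35 splits, highest other 70). The same held for the 79 in slincR morphants (1 of 35, highest other 0) and the 92 changed by the morpholino with TCDD (1 of 35, highest other 3). A share of 1 of 35 is the smallest that the design can give, which makes chance less likely for these counts but does not exclude it. The split with 70 genes amounts to exchanging ConMO_DMSO 1 and ConMO_TCDD 3, which sorts the 8 libraries by their share of reads in no gene (12.78% to 14.44% against 14.99% to 16.06%). For the 31 genes changed by the morpholino in DMSO, 2 of 35 splits gave as many, so the splits do not argue against chance there. The highest other, 167 genes, exchanged ConMO_DMSO 2 and slincRMO_DMSO 4 and points to a structure of the samples that goes with the same share: this split also sorts the libraries by it (14.33% to 15.20% against 12.78% to 13.39%). On the second principal component ConMO_DMSO 2 (25.9) lies with slincRMO_DMSO 1 to 3 (23.6 to 24.1). For the interaction the real count is 0, so that all 100 drawn splits reach it by construction and say nothing about chance. The highest other, 93 genes, moved ConMO_DMSO 2 and 3 and slincRMO_DMSO 2 and 4 and also points to a structure of the samples. It depends on the number drawn, which was 100, then 60 and then 100 again: the first 60 draws had a highest other of 3. What sets the share of reads in no gene was not tested.

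With that share as a covariate, 283, 130, 99 and 287 genes passed for TCDD in control and slincR morphants and for the morpholino in DMSO and TCDD, which held 114 of 128, 79 of 79, 31 of 31 and 92 of 92. The share higher was 51.2%, 73.1%, 20.2% and 28.6%. Of the named calls, those of lyz, IFITM5 and ccl34b.1 for TCDD in control morphants were lost and 0 reversed. The lists past the threshold were 11, 10, 5, 4 and 1. For TCDD in control morphants the ribosomal protein list turned upward, with adjusted p = 0.741.

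DESeq2 gave 264, 165, 95 and 247 genes for TCDD in control and slincR morphants and for the morpholino in DMSO and TCDD, with 94 shared by both TCDD contrasts. The share higher moved from 75.8%, 81%, 12.9% and 18.5% to 66.3%, 70.9%, 33.7% and 32.8%. Only the 8 samples compared gave 69, 125, 17 and 180, and no low-count filter gave 54 in DMSO. An adjusted p under 0.01 left 59, 16 and 27 for TCDD in control morphants and the morpholino in DMSO and TCDD. An absolute log2 fold change of at least 1 left 45, 36, 11 and 15, with 27 shared. Leaving out a library gave 70 to 155, 17 to 52 and 22 to 115 genes for TCDD in control morphants and the morpholino in DMSO and TCDD. The morpholino in TCDD embryos fell to 22 without slincRMO_TCDD replicate 2. The lists past the threshold were 1, 3, 0, 0 and 0 with the correlation estimated per list, against 12, 10, 7, 2 and 1. By fry they were 9, 6, 2, 3 and 0. The order is TCDD in control and slincR morphants, the morpholino in DMSO and TCDD, and the interaction. Leave-outs gave 0 to 1 list for the interaction. The comparison of morpholino and TCDD effects turned from −0.05 to 0.04 over the 158 genes past the threshold in either contrast. The cause was not tested, except that stricter thresholds pass fewer genes by construction.

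Kept under all 24 planned settings other than the stricter thresholds were 16 of 28 named calls for TCDD in control morphants, 15 of 26 in slincR morphants, 9 of 18 for the morpholino in DMSO and 10 of 24 with TCDD, and 0 reversed. The call of sox9b with TCDD in control morphants, counted apart from these, also held under those 24. The counts of named calls include the lincRNA ENSDARG00000097714, chosen after its values were seen, whose call was kept under all 24 in each of these contrasts. Counted apart were ccl34b.1 for TCDD in control morphants, ponzr3 in slincR morphants and ENSDARG00000097834 for the morpholino in DMSO, likewise chosen after their values were seen. Their calls were lost under 11, 7 and 0. No pairing of the samples by replicate number was detected. Of 16 samples 4 matched their own number best, and correlations of the same number ran from −0.18 to 0.13. This does not exclude that samples with the same number were prepared together. A replicate block gave 108, 86, 30, 109 and 0 genes. Leave-outs were not run for the comparison of morpholino and TCDD effects, where they would unbalance the splits. Depth limits genes such as the lincRNA, with 4 counts over 4 libraries.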

Other observations

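The genes below, other than named ones, were chosen after their values were seen, and so were their tests.

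The 5 complement genes lower without TCDD had a median of −0.34 in slincR morphants with TCDD, where 2 passed. All 5 were negative there.

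The small respiratory chain subunits were also lower with TCDD in slincR morphants, with a median of −0.24 (−0.32 to −0.16, quartiles). Of the 51 genes 48 were negative and 0 passed the threshold. In control morphants with TCDD the median was −0.07, with 32 negative and 0 past the threshold. The contrast in slincR morphants shares the slincRMO_TCDD libraries with the one in which these genes were first seen to be lower. With the morpholino in DMSO the median was −0.18. For the interaction the median was also −0.18, with 0 genes past the threshold. Camera gave p = 2.6e-04 for it, and p = 0.19 with an estimated correlation, so a different response of these genes was not shown. The ribosomal protein score differed by −0.28 in DMSO (exact permutation p = 0.0857) and by −0.24 with TCDD in slincR morphants (exact permutation p = 0.0857).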
